A study of Mus musculus with 2 samples.

How the data were processed

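The data were 4 deposited peak lists of H3K4me1 chromatin immunoprecipitation and sequencing from 1 group, neural tube of mice at embryonic day 15.5. There was 1 list for each of the 2 biological replicates, 1 for both replicates pooled and 1 of replicated peaks. Per the labels, replicate 1 came from 78 embryos and replicate 2 from 62 embryos, male and female pooled, with 1 and 2 technical replicates and a size range of 300 to 500. Per the file headers (the accompanying description of each file), the lists are narrowPeak files on mm10, peaks were called on each replicate and on the pool, and the replicated list was derived from these lists. The aligner, the peak caller and its threshold, and the control are not given in the sources used here.

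In each deposited list a peak has a fold enrichment, made by the authors and read here as a linear ratio over the caller's background, which no source used here defines, running from 1.30 to 12.3 over all lists. The authors also gave the −log10 of each peak's p-value, never under 2.01, and the −log10 of its q-value. The deposited score, a whole number scaled to at most 1000, was not used for any result. These are values of single peaks and were used only to describe, rank or filter peaks within a list. The lists hold no counts, so depth per sample is unknown, and a weakly marked region in the shallower library can be missing from its list. Missing peaks are therefore not evidence that the mark was absent.

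Peaks on chromosomes 1 to 19, X and Y were used. Between 2 and 5 peaks per list on sequences not placed on a chromosome were left out. The reference was the GRCm38 assembly, whose chromosomes share the mm10 coordinates, with GENCODE release M21. It gave 21938 protein-coding gene records with 93513 annotated TSSs. A gene symbol was used once in the list tests, leaving 21911 genes, and the TSS of a gene was the 5′ end of its annotated span. All lists of genes and consensus sites, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made after seeing them.

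Peaks were called shared when their overlap was at least 50% of either peak. Observed overlaps and positions were set against 100 circular shifts of the peaks along each chromosome over bases outside assembly gaps of at least 1000 bp. A peak's position was its summit, and a summit within 1 kb of a TSS was counted as promoter before exon, intron or intergenic. For gene lists, the percent of TSS ± 25 kb covered by merged peaks was taken per gene, and the median of a list was set against 100000 random lists (10000 for olfactory receptor genes) of other genes matched on the number of TSSs in the window. Contrasts between sets of genes were differences of medians with 100000 permutations of gene labels, all two-sided. Hox genes were compared in TSS ± 2 kb. Profiles around the TSS used steps of 100 bp over 5 kb to each side. For consensus sites, windows of 200 bp to each side of summits over 2 kb from a TSS were set against as many windows outside all pooled peaks, on the same chromosome and in the same 2% bin of GC content, by Fisher's exact test. Benjamini-Hochberg adjustment was made over the 27 lists and over the 20 sites, and an adjusted p under 0.05 was called.

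The named genes were the 2 members of highest and the 1 of lowest cover in each list, with ties by alphabet, the 15 genes of highest cover genome-wide among the top 2% in each replicate alone, at most 1 per run of such genes with overlapping windows, the 5 peaks of highest fold enrichment and the 5 widest, and the Hox genes at the extremes. The lists covered neural progenitor and radial glia, dorsoventral progenitor, spinal interneuron, motor neuron, pan-neuronal, transmitter, axon guidance, astrocyte, oligodendrocyte and patterning signal genes (the 10 neural lists), anterior, central and posterior Hox genes, forebrain and eye-field factors, sensory ganglion and neural crest, meninges with fibroblasts and cartilage, endothelial, microglia and myeloid, and erythroid genes, 6 lists of distant tissues, housekeeping genes and olfactory receptor genes. They are textbook lists, and a gene can be in more than one.

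The alternatives were the peaks of each replicate alone in place of the replicated list (leaving out the other replicate), peaks with −log10 q of at least 2, peaks of at least 3-fold enrichment, the pooled list, other overlap rules, other windows and other matching. Alternatives added after the data were seen used only replicated peaks that meet a peak of each replicate, 1 gene per run of overlapping windows, genes outside chromosome X, cover relative to the promoter GC decile, or windows under 10% repeat-masked. The steps were tested on simulated data. On the 21938 genes, 6% of random lists had p under 0.05, and lists raised by 2, 5 and 10 percentage points of cover were found in 11.5%, 44.5% and 98% of draws. For these lists, cover values were shuffled over genes and the matching classes were drawn at random. Matching on TSS number and windows shared by neighbouring genes were therefore not part of this check. Of contrasts with no difference, 7.5% had p under 0.05, and no planted consensus site was missed. Analyses were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with Matplotlib 3.10.9.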

Results

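Monomethylation of lysine 4 on histone H3 (H3K4me1), a chromatin mark known from enhancers and from the sequence flanking active promoters, was mapped by chromatin immunoprecipitation and sequencing in mouse neural tube at embryonic day 15.5. The neural tube is the embryonic structure that forms the brain and the spinal cord. The 2 biological replicates, made from 78 pooled embryos for replicate 1 and 62 pooled embryos for replicate 2, form 1 group with no second condition, so the comparisons below set replicate against replicate, peaks against shifted positions, and gene list against gene list. Replicate 1 had 219875 peaks on the assembled chromosomes, covering 4.39% of the genome outside assembly gaps. Replicate 2 had 172737 peaks covering 3.05%. The authors' list for both replicates pooled held 220873 peaks, and their replicated list, used for all results unless another is named, held 138798 peaks with a median width of 554 bp and covered 4.08%. The lists hold no read counts, so the sequencing depth behind each peak is unknown and no counting interval is given. Coordinates are on mm10 and counted from 1.

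Genes of the neural lineage had more H3K4me1 around their transcription start sites (TSSs) than genes of unrelated tissues. Over 178 genes of the 10 neural lists, the median share of the window TSS ± 25 kb covered by replicated peaks was 12.7%. Over 86 genes of the 6 lists for skeletal muscle, heart, liver, intestine and pancreas, epidermis and germ cells it was 3.73%. The difference of 9.01 percentage points had p = 1e-05 in a two-sided permutation test of gene labels, the smallest value that 100000 permutations can give. It was 17.25 points in TSS ± 10 kb and 5.16 in TSS ± 50 kb, each with the same p. With the peaks of each replicate alone, the neural and the non-neural medians were 13.5% and 4.04% in replicate 1 and 9.31% and 2.45% in replicate 2. The difference did not hold for every single list. Neural list medians ran from 6.82% for transmitter genes to 20.7% for axon guidance genes, and the skeletal muscle list had 12.36%. Housekeeping genes, in neither set, had 11.8%. Median promoter GC of the 8 neural lists called in the test of single lists ran from 49.4% for astrocyte genes to 59.98% for neural progenitor genes, against 51.2% over all genes. After the median of all genes in the same decile of promoter GC content was subtracted, a step chosen after seeing the data, the difference was 2.82 points (permutation test, p = 0.0141). Genes are not replicates, so these p-values describe genes within these peak lists.

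Among single lists, progenitor, guidance and signalling genes stood highest outside the Hox clusters. Neural progenitor and radial glia genes had a median cover of 17.5%, led by Notch1, a receptor that keeps progenitors undifferentiated, at 46.0%, and by Nes, the intermediate filament of neural stem cells, at 42.0%. Prom1 was lowest of the 20 at 4.39%. Axon guidance genes reached 20.7%, with the ephrin Efnb3 at 42.0% and Nfasc at 35.9%, while Robo1, a Slit receptor, had none. Patterning signal genes had 17.9%, led by the Hedgehog receptor Ptch1 at 37.2% and Notch2 at 34.8%, and Rarb was lowest at 4.54%. The astrocyte list had 15.7%, with the transcription factor Nfix at 46.2%, the glutamate transporter gene Slc1a2 at 26.3% and Tnc at 3.00%. In the oligodendrocyte list, with a median of 11.3%, Bcan had 32.9%, Sox8 had 26.5% and the myelin gene Plp1 on chromosome X had none. The windows of Bcan and Nes, both on chromosome 3, overlap, so their values are not independent.

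Dorsoventral progenitor factors had a median of 10.9%, from Pax7 at 23.1% and Prdm12 at 16.3% to Dbx1 at 2.13%. Spinal interneuron factors had 11.2%, with Lmx1b at 39.9% and Lbx1 at 38.0%, both factors of dorsal interneurons, and Tlx1 at 5.36%. With the peaks of replicate 2 alone Lmx1b had 21.8%. Pan-neuronal genes had 10.8%, with the splicing factor Rbfox3 at 37.7%, Stmn1 at 25.7% and Elavl4 at 1.61%, and their median was 6.93% with the peaks of replicate 2 alone. Outside the neural lists, housekeeping genes had 11.8% (Ywhaz at 26.2%, Chmp2a at 24.8%, B2m at 1.42%), skeletal muscle genes had 12.36% (Casq1 at 27.4%, Des at 24.1%, Ttn none), and forebrain and eye-field factors had 9.29%. Anterior Hox genes had 63.9% and central Hox genes 65.1%. The 1134 olfactory receptor genes had a median of 0, and 1038 of them had no peak in the window. The median of all 21911 protein-coding genes was 5.91%.

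Each list was tested against 100000 random lists (10000 for olfactory receptor genes) of the same size matched on the number of TSSs in the window, in a two-sided permutation test with Benjamini-Hochberg adjustment over the 27 lists. The 14 lists whose medians are given above were called, 13 higher and the olfactory receptor genes lower, with adjusted p between 0.00018 and 0.0326. When the random lists were matched on promoter GC instead, 4 lists stayed higher and none was lower: anterior Hox, central Hox, axon guidance (adjusted permutation p = 0.00828) and astrocyte genes (0.0120). With no matching, 7 were higher and 1 lower. The call of the forebrain list ended in every alternative except the stricter q-value and genes outside chromosome X alone. That of the skeletal muscle list ended without replicate 1, at 3-fold, in TSS ± 10 kb and ± 50 kb, over the gene body and with no matching, and that of the oligodendrocyte list in these 3 windows and with no matching. The call of the pan-neuronal list ended without replicate 1 and with no matching, that of housekeeping genes in TSS ± 50 kb and with no matching, and those of the dorsoventral and interneuron lists with no matching.

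The other 13 lists were not called. Motor neuron genes had a median of 8.96% (adjusted permutation p = 0.0580), led by Onecut2 at 16.7% and Etv4 at 16.1%, with Nos1 at 1.52%. Transmitter genes had 6.82%, although the GABA transporter gene Slc6a1 reached 53.7% and Slc32a1, which loads GABA into vesicles, 28.0%, while the receptor gene Gabrb3 had none. Posterior Hox genes had 17.5% (adjusted permutation p = 0.352), and were called higher in TSS ± 50 kb, with 28.1%, and with no matching. In TSS ± 10 kb, motor neuron genes were called higher, with 18.1%, and germ cell genes lower, with a median of 0. Motor neuron genes were also called higher with only peaks that meet both replicates (8.52%, adjusted permutation p = 0.0480), an alternative chosen after seeing the data. For cell types that adjoin or enter the neural tube, sensory ganglion and neural crest genes had 6.43%, genes of meninges, fibroblasts and cartilage 6.65%, endothelial genes 6.29%, microglia and myeloid genes 5.75% and erythroid genes 2.54%. The highest members of these lists were Tfap2a (18.5%), Col2a1 (34.2%), Eng (20.7%), Fcer1g (16.6%) and Nfe2 (22.0%), and their lowest were Scn10a, Col3a1, Csf1r and Alas2, with none, and Emcn (0.582%). Among lists of distant tissues, cardiac genes had 5.42%, hepatocyte genes 1.90%, intestine and pancreas genes 0.938%, epidermis genes 2.04% and germ cell genes 5.40%. With the peaks of replicate 2 alone, germ cell genes had 3.28%, intestine and pancreas genes 0.606% and erythroid genes 1.42%, against 4.50% over all genes. Afp, Fabp2, Dsg1a and Dazl had no replicated peak in their windows, and Foxa3 (23.3%), Cpa1 (24.4%), Grhl3 (19.1%), Nanos2 (30.5%) and Myl7 (21.4%) were the highest members. Of these, Fcer1g, Nfe2, Cpa1 and Nanos2 had no replicated peak in TSS ± 2 kb. The windows of Foxa3 and Nanos2, both on chromosome 7, overlap. With the peaks of replicate 2 alone Grhl3 had 10.7% and Tfap2a 11.9%.

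**Figure D1:**
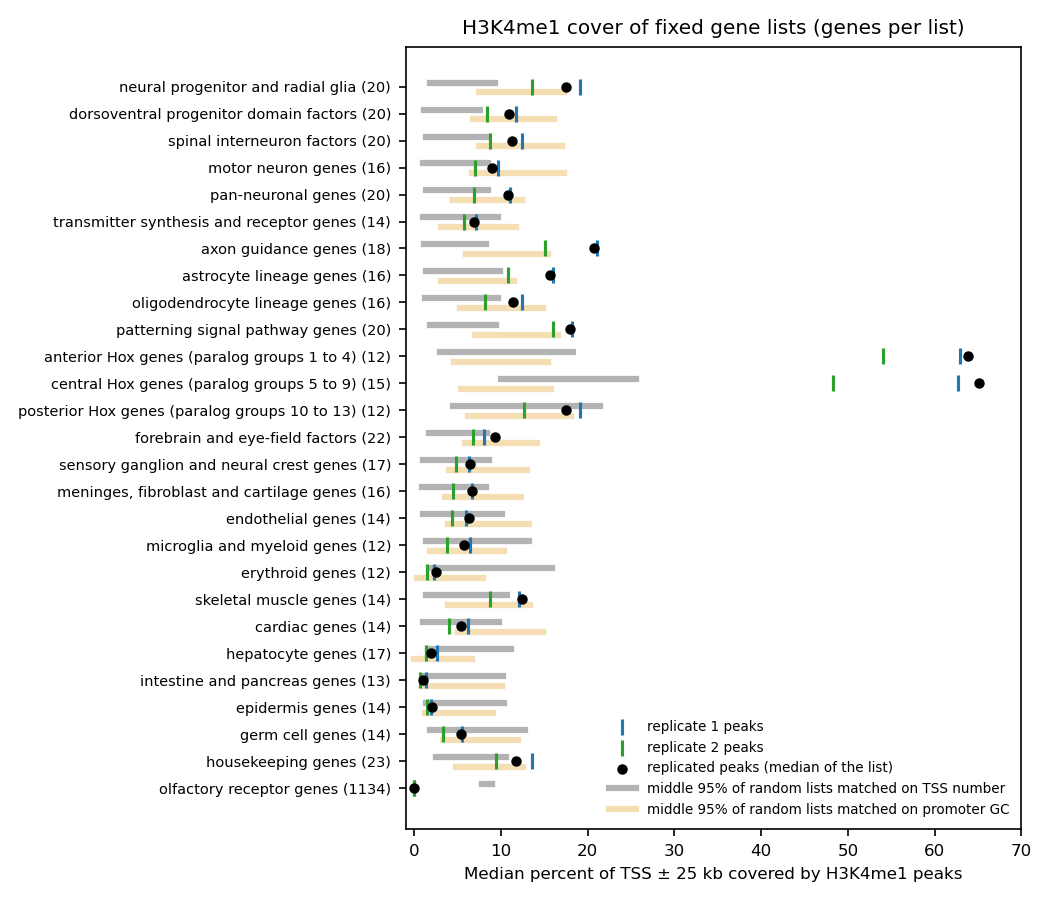
Median percent of the window TSS ± 25 kb covered by H3K4me1 peaks (x axis) for each of the 27 gene lists (y axis, number of genes in brackets). Black points are the replicated peaks, blue and green ticks the peaks of replicates 1 and 2 alone, grey and yellow bars the middle 95% of random lists matched on TSS number and on promoter GC; the anterior and central Hox lists lie far to the right of both bars, at 63.9% and 65.1%.

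The Hox genes, whose order in each cluster follows their order of expression along the body axis, had H3K4me1 over most of the anterior and central parts of the clusters and less at the posterior ends. In the window TSS ± 2 kb, the 8 genes of paralog groups 1 to 3 had a median cover of 72.6%, the 19 genes of groups 4 to 9 had 67.2%, and the 12 genes of groups 10 to 13 had 22.3%. Hoxa5, on chromosome 6 with its TSS at 52204587, was covered over the whole window, and Hoxc12, on chromosome 15 with its TSS at 102936757, had no cover. The difference between groups 4 to 9 and 10 to 13 was 44.9 percentage points (two-sided permutation test, p = 0.0104). With the peaks of replicate 2 alone it was 21.4 points (permutation test, p = 0.0771), and with those of replicate 1 alone 40.01 points (permutation test, p = 0.0120). With only the replicated peaks that met a peak of each replicate, a choice made after seeing the data, it was 25.9 points (permutation test, p = 0.0512). In the wider window of 25 kb to each side, Hoxb3 (chromosome 11, 89.8%) and Hoxb4 (84.6%) ranked first and second of all genes. Hoxb13 had 2.17%, and 4.64% with the peaks of replicate 1 alone. In TSS ± 2 kb its cover was 21.5%. The TSS itself lay in a replicated peak for 7 of 12 genes of groups 10 to 13 and for 8 of 19 of groups 4 to 9. The lower cover of the posterior genes was thus not a lack of peaks at their TSSs. Neighbouring Hox genes share windows and peaks, so they are not independent. The TSS used was the 5′ end of the annotated gene, which for Hoxc5 lies at 102967443 on chromosome 15 beside that of Hoxc10 at 102966796. Likewise Hoxd3 and Hoxd4 start at 74711927 and 74711929 on chromosome 2, and Hoxa3 at 52213336 on chromosome 6, between Hoxa6 and Hoxa7, and these genes enter the medians of their groups.

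**Figure D2:**
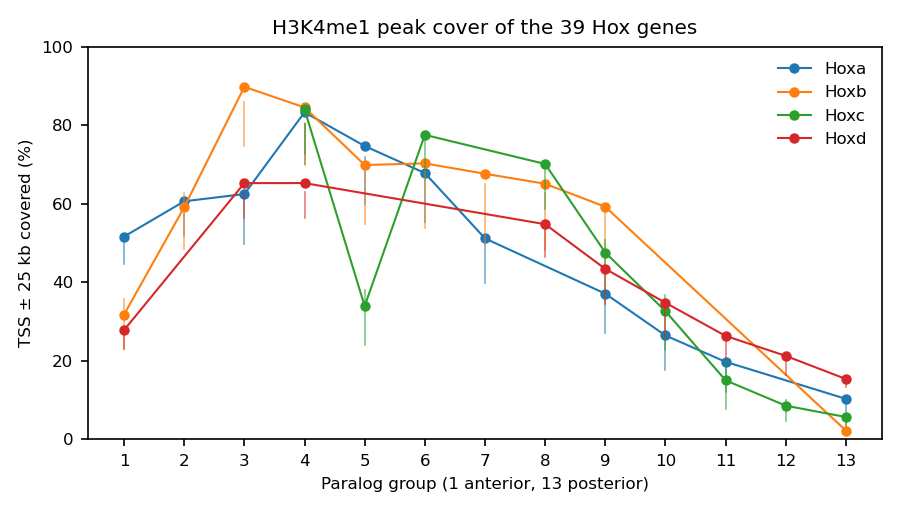
Percent of the window TSS ± 25 kb covered by replicated H3K4me1 peaks (y axis) for the 39 Hox genes by paralog group (x axis), 1 colour per cluster; thin vertical lines run between the values with the peaks of replicate 1 and of replicate 2 alone. Cover is highest in groups 3 and 4 (Hoxb3 at 89.8%) and falls to between 2.17% and 15.3% in group 13. Windows of genes at a cluster's end also take in sequence outside it. In TSS ± 2 kb group 13 had from 21.5% (Hoxb13) to 42.6% (Hoxc13).

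Factors of the spinal cord and factors of the forebrain had similar medians in the main window, and their difference did not pass the test. The 56 genes of the dorsoventral, interneuron and motor neuron lists had a median cover of 10.4% and the 22 forebrain and eye-field factors 9.29% (Lhx2 at 14.9%, Eomes at 13.3%, Otx2 at 2.79%). The difference of 1.08 percentage points had p = 0.332 (two-sided permutation test). It was 2.31 points with the peaks of replicate 1 alone (permutation test, p = 0.0944) and 0.764 with those of replicate 2 alone (permutation test, p = 0.523). In the window TSS ± 10 kb the difference was 5.63 points (permutation test, p = 0.0196), and in TSS ± 50 kb it was 2.18 points (permutation test, p = 0.0139), the spinal cord factors being higher in each.

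At housekeeping genes H3K4me1 flanked the TSS and was low on it, while at forebrain factors it lay on the TSS itself. Of 138 annotated TSSs of 23 housekeeping genes, 15.2% lay in a replicated peak, and the share rose to 58.0% at 1200 bp upstream and 79.7% at 1500 bp downstream. Of 81 TSSs of the forebrain factors, 61.7% lay in a peak. The 10 neural lists pooled had 37.3% at the TSS and 41.3% at 700 bp downstream, and with 1 TSS per gene the single lists ran from 10% for pan-neuronal genes to 80% for dorsoventral factors. Over all 93513 TSSs of protein-coding genes the share was 16.8% at the TSS, 30.1% at 600 bp upstream and 38.5% at 1000 bp downstream, so the highest flank exceeded the lowest point within 500 bp of the TSS by 2.29-fold. The ratio was 2.18 with the peaks of replicate 1 alone and 2.59 with those of replicate 2 alone. Olfactory receptor genes had a peak on 0.0761% of their 2627 TSSs. TSSs of one gene often lie close together and are not independent, and no test was made on the profile.

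**Figure D3:**
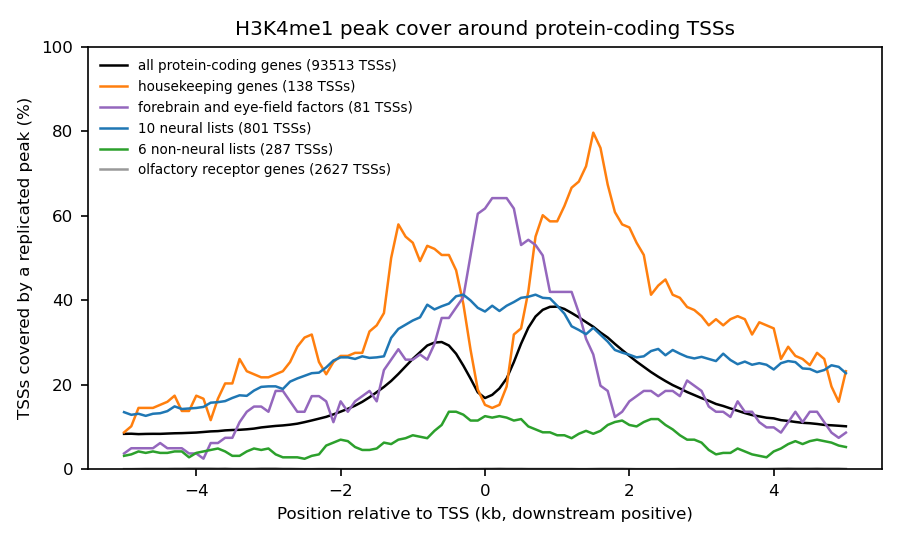
Share of annotated TSSs covered by a replicated H3K4me1 peak (y axis, percent) at each position from 5 kb upstream to 5 kb downstream of the TSS (x axis, kb), 1 line per set of genes. Housekeeping genes dip to 14.5% at 100 bp downstream and reach 79.7% at 1500 bp, whereas forebrain and eye-field factors reach 64.2% at 100 bp downstream.

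Most replicated peaks lay away from promoters, in introns and between protein-coding genes. Introns of these genes held 50.6% of summits (35.6% ± 0.67 over 100 circular shifts of the peaks along each chromosome, mean ± SD), and their exons held 3.77% (2.89% ± 0.084). Sequence outside protein-coding genes, which can lie in other annotated genes, and over 1 kb from a TSS held 29.0% (57.5% ± 0.79). Within 1 kb of a protein-coding TSS lay 16.6% of summits (4.07% ± 0.14 for shifted peaks), and at 1 to 5 kb 19.2% (11.1% ± 0.32). Over 50 kb from a TSS lay 25.5% (47.0% ± 1.1). For each of these the two-sided permutation p against the shifts was 0.0198, the smallest they can give. At 5 to 50 kb, the share of 38.7% was within the spread of the shifts (37.9% ± 0.73, permutation p = 0.317). That share was above the shifts with the peaks of replicate 1 alone (40.7%, permutation p = 0.0198) and below them with peaks of at least 3-fold enrichment (35.0%, permutation p = 0.0198) and with the TSSs of all annotated genes (45.9% against 53.9%, permutation p = 0.0198). Peaks within 1 kb of a TSS had a median fold enrichment of 3.78 and a median width of 714 bp, and peaks over 50 kb away 3.02 and 507 bp, by the authors' values per peak.

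Distal peaks, with summits over 2 kb from a protein-coding TSS, differed from control windows in the consensus sites they held. The NFI palindrome, a site of the nuclear factor I family that acts in glial development, was in 0.878% of 104604 summit ± 200 bp windows and in 0.241% of GC-matched windows outside all pooled peaks, a ratio of 3.64 (95% interval 3.17 to 4.19). The core of the insulator factor CTCF had a ratio of 3.30 (2.90 to 3.76) and the MEF2 site 2.28 (2.02 to 2.57). The homeodomain site TAATTA was in 11.8% of peak windows against 6.15%, a ratio of 1.91 (1.86 to 1.97), the composite site of PBX and HOX proteins had 1.66 (1.59 to 1.74), the POU octamer 1.41 (1.33 to 1.49) and the RFX half-site 1.40 (1.35 to 1.45). Of the E-boxes bound by proneural factors, CAGCTG had a ratio of 1.37 (1.35 to 1.39) and CAGATG 1.062 (1.05 to 1.08), and the SOX core had 1.13 (1.11 to 1.14). The ratio was 1.197 for TEAD, 1.10 for GATA, 1.10 for p53 and 1.04 for AP-1. The call of AP-1 ended without replicate 1, around the peak middle, over 10 kb from a TSS and with peaks of both replicates, and those of AP-1 and p53 ended in the 20000 distal peaks of highest fold. The site of the GLI factors, which act in Hedgehog signalling, was less frequent in peaks, at 0.721 (0.627 to 0.828). In total, 14 of 20 consensus sites were more frequent and 1 less frequent by Fisher's exact test with Benjamini-Hochberg adjustment over the 20. Windows are not replicates, so intervals and tests describe windows within this list. With the peaks of replicates 1 and 2 alone, ratios were 3.28 and 3.35 for NFI, 2.70 and 3.12 for CTCF, and 2.04 and 1.92 for MEF2. They were 1.70 and 1.74 for TAATTA and 1.48 and 1.60 for PBX-HOX, some below the intervals above. TEAD was slightly higher, at 1.23 and 1.21.

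The sites for ETS (1.03), the SRF box (1.02), HNF4 (1.02) and retinoic acid receptors (1.11) did not pass the test, nor did HNF1, found in 1 peak window and no control window. The retinoic acid receptor site passed in 5 alternatives, with 1.51 in windows around the peak middle and 1.61 within 100 bp of the summit. Repeat-masked bases made up 11.7% of the peak windows and 33.1% of the control windows. With peak and control windows under 10% masked, a limit chosen after seeing the data, 12 sites were more frequent and 4 less frequent by Fisher's exact test. There AP-1 turned to 0.899 (adjusted p = 5.2e-07, Fisher's exact test), ETS to 0.826 and HNF4 to 0.846, all called lower, and TEAD was 1.04 and the p53 site 0.987, neither called. Within 100 bp of the summit the CTCF core had a ratio of 0.845 (adjusted p = 0.147, Fisher's exact test). With the peaks of replicate 1 alone 2 sites were less frequent.

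**Figure D4:**
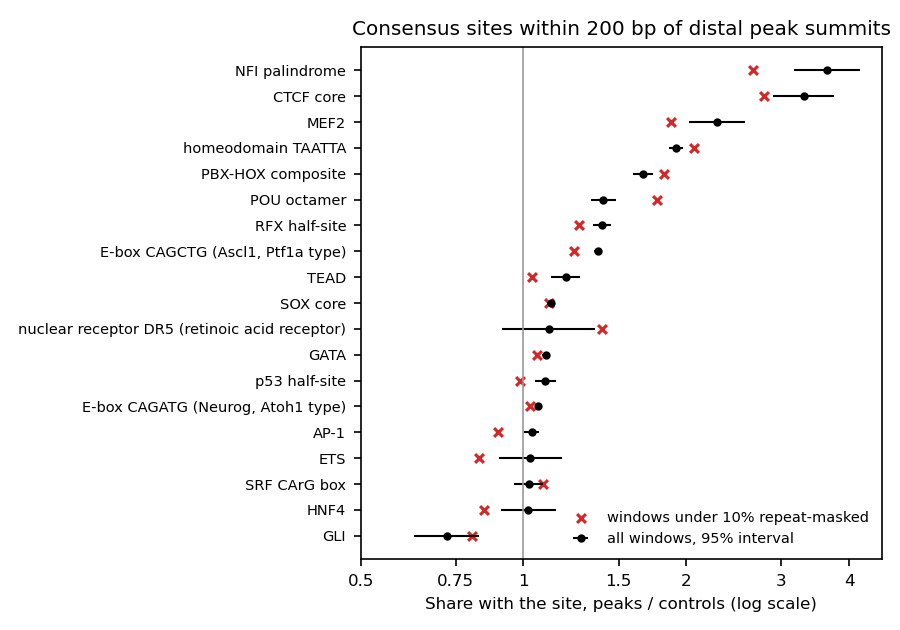
Ratio of the share of distal peak windows to the share of GC-matched control windows that hold each consensus site (x axis, log scale) for the 19 sites found in both (y axis). Black points with bars are the ratios with 95% intervals over all windows and red crosses the ratios in windows under 10% repeat-masked; the NFI palindrome (3.64) and the CTCF core (3.30) are highest and GLI (0.721) is lowest.

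Chromosome X had far fewer peaks than any autosome, and chromosome Y had none in any list. The replicated list held 5.71 peaks per Mb on X against 57.5 per Mb over the autosomes, a ratio of 0.0993, and single autosomes ranged from 42.2 on chromosome 3 to 88.9 on chromosome 11. The ratio was 0.108 with the peaks of replicate 1 and 0.0920 with those of replicate 2. The median cover of TSS ± 25 kb was 0 for genes on X and 6.31% for all other genes, those on Y included. The embryos were male and female pooled, and no test was made across chromosomes.

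**Figure D5:**
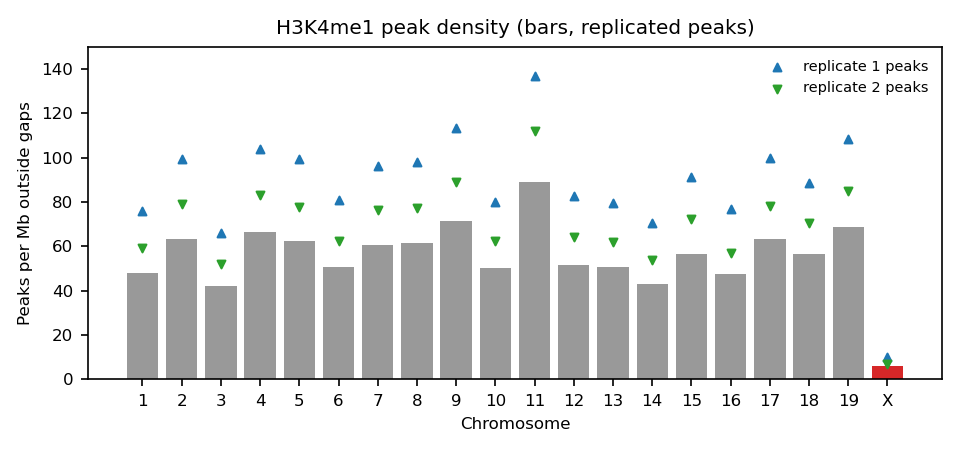
H3K4me1 peaks per Mb outside assembly gaps (y axis) on each chromosome (x axis). Bars are the replicated peaks, with X in red, and triangles the peaks of each replicate alone; X, at 5.71, lies below the lowest autosome, chromosome 3 at 42.2.

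Hox genes were among those with the broadest H3K4me1. By the rule for genome-wide names, the 15 genes with the highest cover of TSS ± 25 kb were Hoxb3 (89.8%), Hoxc4 (84.1%), Hoxa4 (83.3%), Gm28230 in the Hoxd cluster (74.2%), G430095P16Rik (70.2%), the protocadherin gene Pcdhgc5 (62.8%), Cirbp (59.5%), Thtpa (59.5%), Cxxc5 (58.5%), the corepressor gene Tle3 (58.5%), Coro2b (57.6%), Bahcc1 (57.4%), Tshz1 (56.9%), the retinoic acid receptor gene Rara (55.7%) and Nr1d1 (55.7%). The peak of highest fold enrichment, 12.1-fold in the pooled data, 10.9-fold in replicate 1 and 11.95-fold in replicate 2, lay in Mepce on chromosome 5 from 137781331 to 137785569, with its summit in an exon. It was followed by peaks in Inpp5e (11.7-fold), Pcgf2 (11.7-fold), Kmt5b (11.6-fold) and Ddost (11.5-fold), each with its summit 1.15 to 4.62 kb from the TSS. The widest peak spanned 15329 bp in an intron of Gse1 on chromosome 8, from 120507401 to 120522729, with a fold enrichment of 6.53, and the next widest lay in Zmiz1, Lrp8, Rara and Mtss1.

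Peaks of replicate 2, whose list was the shorter, were shared more often than those of replicate 1. Shifted peaks differed in the same direction. With an overlap of at least 50% of either peak counted as shared, 51.6% of replicate 1 peaks (113468) and 74.9% of replicate 2 peaks (129325) were shared, against 4.73% ± 0.19 and 6.22% ± 0.26 for 100 circular shifts (mean ± SD, one-sided permutation p = 0.0099, the smallest they can give). With an overlap of at least 50% of both peaks, 34.1% and 43.4% were shared, against 1.33% ± 0.050 and 1.70% ± 0.064. The covered bases had a Jaccard index of 48.4%, against 2.12% ± 0.11. Of the 50000 replicate 1 peaks of smallest p, 94.1% met a peak of replicate 2, and of those of replicate 2, 96.5% met a peak of replicate 1. Between these 50000 peaks of each replicate themselves, 66.2% and 72.8% were shared. Across 110249 pooled peaks that met a peak of each replicate, the authors' fold enrichments had a Spearman rho of 0.558 and a Pearson r of 0.676. This is a correlation across peaks, which are not independent replicates.

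The replicated list was a subset of the pooled list and kept its strong and wide peaks. All 138798 of its peaks were identical to pooled peaks, and they made up 62.8% of the pooled list, from 16.1% of the lowest decile by fold enrichment to 100% of the highest, and from 16.1% of peaks up to 250 bp wide to 100% of those over 2000 bp. Every one of the 110249 pooled peaks that met a peak of each replicate was listed. A further 28549 listed peaks (20.6%) did not meet one in each replicate under that rule, 27724 of them not even by 1 bp, and 1236 met none in either. These had a median fold enrichment of 2.63, against 3.41 for listed peaks with both replicates and 2.36 for the 82075 pooled peaks that were not listed.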

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

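No test was made on these peaks. Outside the chromosomes used for the results, the replicate 1 list held 5 peaks on 3 sequences that are not placed on a chromosome, with fold enrichments from 2.40 to 4.10. The pooled list held 5 such peaks on 4 sequences, with fold enrichments from 1.34 to 3.59. They are given because these peaks enter no comparison of the report, and their numbers show nothing about signal on these sequences. The replicate 2 list and the replicated list held 2 each.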

How the results depend on the processing

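The alternatives with only peaks that meet a peak of each replicate, with 1 gene per run of windows, with genes outside chromosome X, with cover relative to the promoter GC decile, and with windows under 10% repeat-masked were chosen after seeing the data. Where a result below changed, the cause was not tested. Of 143 alternatives over 21 results of the design, 12 moved past the limit set for them, 3 reversed, 3 gained and 2 lost a call. The others kept their direction and side of the threshold or stayed within that limit. For counts of lists or sites the limit was a fixed ratio. For rho and the share of pooled peaks it was an interval over peaks, and for the X and flank ratios the SD between replicates. Spearman rho of fold enrichment was 0.549 with −log10 q of at least 2 and 0.615 on −log10 p. The share of pooled peaks was 50.8% for those that meet both replicates by 1 bp and 69.6% with −log10 q of at least 2. The X to autosome ratio was 0.0781 at 3-fold. The share of summits 5 to 50 kb from a TSS was 38.8% to 40.7% with 1 replicate left out, 35.0% at 3-fold, 45.9% with all annotated genes and 37.3% with peaks of both replicates, below the shifts at 3-fold and with all annotated genes and within their spread with peaks of both replicates. The flank to TSS ratio was 2.18 to 2.59 with 1 replicate left out. Of the gene lists, 2 were lower in TSS ± 10 kb, 7 higher with no matching, and 4 higher and 0 lower with promoter GC matching, where spinal interneuron factors (11.2%) fell just under the random median. Spinal cord minus forebrain factors gave 5.63 points in TSS ± 10 kb and 2.18 in TSS ± 50 kb. The Hox difference was 21.4 to 40.01 points with 1 replicate left out and 25.9 with peaks of both replicates. Sites less frequent in peaks numbered 1 to 2 with 1 replicate left out and 4 with the repeat limit. Single sites turned for CTCF (0.845, summit ± 100 bp), AP-1 (0.956 in the 20000 distal peaks of highest fold, 0.899 with the repeat limit), SRF (0.946 to 0.981 with 1 replicate left out) and, with the repeat limit, ETS (0.826), HNF4 (0.846) and p53 (0.987). Without being called, HNF4 was also under 1 without replicate 2 (0.921), around the peak middle (0.954) and over 10 kb from a TSS (0.985), and SRF over 10 kb from a TSS (0.989), in the 20000 distal peaks of highest fold (0.962) and with peaks of both replicates (0.982). Of 351 alternatives for single lists 35 lost a call in the same direction and 5 gained one, besides the interneuron list above, which also lost its call, and of 152 for single sites 6 lost a call in the same direction and 6 gained one, besides those that turned. HNF1 has no ratio, as no control window held it. No paired analysis was possible because there is 1 group. Depth is unknown, so whether the shorter list of replicate 2 comes from fewer reads is open.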

Other observations

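The tests of 28 gene families, of site positions around summits and of all explanations below, except those of repeat-masked sequence on chromosome X and of promoter GC at the TSSs of developmental factors, were chosen only after the result was seen. Families were taken by symbol and set against random lists as in the report. Ephrins and their receptors, which guide axons, had a median cover of 19.2% over 22 genes, with Efna2 at 42.0%, and were higher both with TSS-number matching (adjusted permutation p = 0.00014) and with promoter GC matching (0.0371). The 80 ribosomal protein genes had 13.1% and were higher under both (adjusted permutation p = 0.00386 and 0.00028). Histone cluster genes, with 13.7%, were higher only under GC matching (random median 5.16%) and lay under the random median of 15.5% with TSS-number matching. Keratin genes, with 1.94%, and cytochrome P450 genes, with a median of 0 and 58 of 100 without a peak, were lower under both. Semaphorin genes had 15.2%, Wnt genes 14.4% and Sox genes 14.1%, and these 3 were higher only with TSS-number matching. Of 56 clustered protocadherin genes, 46 had no peak in the window, while Pcdhgc5 had 62.8% and its neighbour Pcdhgc4 54.1%. Many histone, keratin, cytochrome P450 and protocadherin genes lie in clusters and share windows, so they are not independent. In all, 10 families were higher and 7 lower with TSS-number matching, and 3 and 3 with promoter GC matching.

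Consensus sites in distal peaks differed in where they lay relative to the summit. The E-box CAGCTG was most frequent at the summit, with 10899 sites within 50 bp and 5758 at 450 to 500 bp, and the NFI palindrome fell from 363 to 91 sites over the same distance. The CTCF core had 78 sites within 50 bp of a summit and 559 at 150 to 200 bp, and the homeodomain site TAATTA had 2397 within 50 bp and 4616 at 150 to 200 bp. No test was made on these counts, and they were not set against control windows. Base composition also changed with distance, with a mean GC content of 50.9% in summit ± 100 bp and 48.8% in summit ± 200 bp. Against GC-matched windows TAATTA had a ratio of 2.11 in summit ± 100 bp and 1.91 in summit ± 200 bp. The counts therefore do not show that this site avoids summits.

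Chromosome X had fewer peaks per Mb than any autosome. Per protein-coding gene the ratio to autosomes was 0.149, and per Mb outside repeat-masked sequence it was 0.124, each below the lowest autosome (0.643 and 0.760), which argues against gene number or repeats as the whole cause, and in the pooled list, before the replicate filter, it was 0.103. The ratio fell as the fold minimum rose, and at 5-fold, with 9 peaks left on X, it was 0.124 of its value at 3-fold, against at least 0.761 for every autosome. Peaks on X may therefore be weaker versions of the same kind of sites, a hypothesis found and tested on the same data. Their median fold enrichment was 2.98, against 3.16 on the autosomes. Whether such sites fall under the caller's threshold more often cannot be seen in lists of called peaks. Whether the lower density on X comes from the control, read mapping or the pooled sexes was not tested, and no biological explanation was tested.

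Higher cover of gene lists was set against the GC content of their promoters. Between neural and non-neural genes a difference of 2.82 points was left after the subtraction given in the report. Of the 13 lists called higher, 4 were also called with promoter GC matching. These values argue against promoter GC as the whole cause of that difference and of these 4 calls. Among the 4 are the anterior and central Hox lists, whose genes share windows and are not independent. Both steps used GC deciles, so GC differences within a decile remained. For the other 9 of the 13 lists promoter GC may be a cause, but GC matching replaced TSS-number matching. All of these 9 except the neural progenitor and patterning lists also lost their call with no matching. The loss of a call alone therefore cannot point to promoter GC. The neural progenitor (17.5%) and patterning lists (17.9%) lay above the middle 95% of GC-matched random lists (up to 17.3% and 16.6%). Neither passed the adjustment (adjusted permutation p = 0.169 and 0.104). The interneuron, forebrain and dorsoventral lists lay close to the GC-matched random medians (11.4%, 9.25% and 10.5%). Genes of chromosome X in the random lists were not needed for the 13 calls. With these genes left out of both the lists and the random lists, the highest adjusted permutation p was 0.0483. Genes of chromosome Y, which had no peak, stayed in the random lists, so their part was not tested. No biological explanation was tested, since the design has 1 group.

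TSSs of forebrain, dorsoventral and interneuron factors often lay inside peaks. With 1 TSS per gene, 43 of 62 (69.4%) did, above the 14.5% to 35.5% of the middle 95% of GC-matched random lists, and the share exceeded that of housekeeping genes (6 of 23, Fisher's exact p = 0.000479), which argues against promoter GC and against several TSSs per gene as the cause. The trait was not one of these factors alone, since, with adjustment over the lists, the share was also higher than in GC-matched random lists (adjusted permutation p at most 0.0359) for neural progenitor (15 of 20), patterning signal (13 of 20), oligodendrocyte (10 of 16), astrocyte (8 of 16), anterior Hox (7 of 12), endothelial (8 of 14) and meninges, fibroblast and cartilage genes (12 of 16), and not for motor neuron (8 of 16) or posterior Hox genes (7 of 12), each at 0.0745. No biological explanation was tested.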
